A study of Mus musculus with 7 samples.

How the data were processed

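Gene expression was measured on 7 Affymetrix arrays in haematopoietic stem cells of the mouse fetal liver at embryonic day 14.5. Of these, 3 came from embryos homozygous for a form of TFIIAα-β that cannot be cleaved (TFIIA nc/nc) and 4 from wild-type embryos. Per the labels' protocols, heterozygous parents were crossed, embryos were genotyped by PCR, and liver cells of littermates with one genotype were combined. The TFIIA nc/nc samples held 2, 2 and 4 embryos, and the wild-type samples 1, 1, 4 and 3. Cells negative for lineage antigens and positive for Sca-1, c-Kit and CD150 were sorted and sorted again, total RNA was taken with TRIzol, and biotinylated cRNA was made with a linear amplification that starts at the 3' end of the transcript. The labels call the samples biological replicates and name no litter, day or batch shared between the genotypes.

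The deposited values are RMA intensities per probe set made in Affymetrix Expression Console, per the submitters' processing notes. The program versions are not given in the sources used here. RMA corrects the background, brings the arrays to similar distributions and summarises the probes of a set. It returns a value for every probe set, transcribed or not, so differences between dim probe sets tend to be understated. The values lay on a linear scale, whereas the plan had assumed log2 values, so log2 was taken with no pseudocount. Array medians were then 3.69 to 3.82. Detection calls, scan dates and scanner files were not used here, so batches of arrays were not tested. The precision of each value is limited by the number of arrays.

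Of 22690 probe sets, 64 controls were left out and 22626 entered the fit. Gene names came from the platform annotation, updated through Entrez identifiers with a RefSeq gene table of assembly GRCm38.p6, which 12369 of 12393 genes matched. That table was used only for names and gene order. A single gene symbol stood beside 20380 probe sets, several beside 691 and none beside 1555. Each gene was represented by the probe set with the highest mean over the 7 arrays among those naming it alone, which gave 12393 genes.

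The genotypes were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, without covariates, on all 7 arrays. The 2-sided p-values were adjusted by Benjamini-Hochberg over the 12393 genes, with a threshold of 0.05. Differences are given as TFIIA nc/nc minus wild type on the log2 scale, with their standard errors (SE), and levels as mean ± SD. Single values were compared by an exact 2-sided permutation test over the 35 assignments of the arrays, whose smallest possible p is 0.0286. A set of 31 gene lists was tested with limma's camera at a preset correlation between genes of 0.01, adjusted by Benjamini-Hochberg over the lists. Camera with an estimated correlation and fry, which tests a list by itself, were the alternatives. The comparison, its test, the lists, the rule for naming genes and the other settings to be tried were fixed before the data were examined.

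The genes named were Gtf2a1, then the 12 genes in each direction with the largest change among those past the threshold with groups that did not overlap. Places left open were filled by smallest p, without X-inactivation or Y-linked genes. In each list up to 3 members with the smallest p were named where none passed; further members named beside them were chosen after their values were seen. The other probe sets of a named gene were checked for the opposite sign where their mean log2 level was at least 5. Only Ccnd1 and Endog had such probe sets, and none had the opposite sign.

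On 20 simulated data sets of 12393 genes with the spread of this comparison and 200 changed genes each, the fit recovered 73.65% of genes changed by 1 on the log2 scale and 98.4% of those changed by 2, with 9.25 false calls per set. The noise was drawn independently for each gene and held no structure shared between arrays. With fewer changed genes the adjustment is stricter, so these shares do not give the recovery expected in this comparison. Lists of 23 unchanged genes simulated with a correlation of 0.184 reached an unadjusted p under 0.05 in 36% of cases with the preset correlation and in 4% with the estimated one. Other settings covered the choice of probe set, filters on dim probe sets, the normalization, the moderation, array weights, the number of embryos pooled, the sex of the embryos, RNA integrity, the replicate number, the threshold and leaving out each array. Settings added after seeing the data were the mean of endothelial genes as a covariate, only the 4 arrays with low endothelial transcripts, and a separate test of probe sets without a single gene name. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.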

Results

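TFIIA is a general transcription factor that stabilises TBP on promoters, and its large subunit, encoded by Gtf2a1, is cut into α and β parts by the protease Taspase1. The series asked how the transcriptome of fetal liver haematopoietic stem cells differs when that cut cannot be made. RNA from sorted stem cells of 3 TFIIA nc/nc and 4 wild-type samples, each 1 to 4 embryos, was measured on 1 array per sample. The arrays correlated pairwise at 0.966 to 0.991 over all probe sets. The 3' minus 5' signal was 1.94 to 2.99 log2 units for actin and 0.71 to 1.41 for Gapdh over the arrays. It differed between the genotypes by 0.298 for actin (exact permutation p = 0.4) and by 0.15 for Gapdh (exact permutation p = 0.486). Amplification from the 3' end also enters this signal, so it does not measure RNA integrity alone. Transcripts of endothelial cells stood apart in 3 arrays. The mean log2 level of 16 endothelial genes was 6.55 and 6.97 in TFIIA nc/nc replicates 1 and 2 and 6.72 in wild-type replicate 1, against 4.097 to 4.404 in the other 4 arrays. Embryo sex also varied. The mean level of Xist, the RNA of the inactive X chromosome, was 3.16 and 3.08 in wild-type replicates 1 and 2 and 7.75 to 9.88 elsewhere, and Y-linked genes averaged 1.54 in TFIIA nc/nc replicate 1 against 3.61 to 5.68 elsewhere.

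Gtf2a1, the targeted gene (Entrez gene 83602), was measured at a log2 level of 5.75 ± 0.52 (SD, n = 3) in TFIIA nc/nc and 4.61 ± 1.03 (SD, n = 4) in wild type. The difference of 1.14 (SE 0.50) did not pass the threshold (limma, Benjamini-Hochberg adjusted p = 0.946). The TFIIA nc/nc samples read 5.17, 6.16 and 5.92 and the wild-type samples 3.61, 5.27, 3.86 and 5.69. The other Gtf2a1 probe sets differed by 0.58 (exact permutation p = 0.114) and −0.22 (exact permutation p = 0.2). A mutation of the cleavage site need not alter the transcript, so these levels do not check the genotype labels. In the list of 7 measured genes of TFIIA, the TBP family and Taspase1, Usf2, a transcription factor, differed by −0.42 (SE 0.17), Tasp1, which encodes Taspase1, by 0.76 (SE 0.34), and Tbp by −0.27. None of the 7 passed in limma over all genes or adjusted over the list alone, and 2 had an unadjusted p under 0.05.

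Galc (Entrez gene 14420), which encodes the lysosomal enzyme that degrades galactosylceramide, gave a lower signal in the TFIIA nc/nc stem cells. Its log2 level was 5.69 ± 0.27 (SD, n = 4) in wild type and 2.16 ± 0.24 (SD, n = 3) in TFIIA nc/nc, 11.6-fold lower (difference −3.54, SE 0.19, limma, Benjamini-Hochberg adjusted p = 0.000171). The fold is an estimate for the signal of this probe set. The TFIIA nc/nc level lay among the dimmest probe sets, where differences tend to be understated. The fold is no bound for the transcript, since a sequence variant under the probes may also lower the signal. All 3 TFIIA nc/nc samples, at 1.88 to 2.31, lay below all 4 wild-type samples, at 5.31 to 5.96. Between 67.1% and 71.6% of probe sets lay below Galc in the wild-type arrays and 9.83% to 25.0% in the TFIIA nc/nc arrays. The other Galc probe sets averaged 2.11 and 1.87 in wild type and differed by −0.09 and −0.19. Galc lies on the same chromosome as Gtf2a1, 5 protein-coding genes away in the gene order of GRCm38.p6. The other measured genes that close, Adck1, Dio2, Tshr and Sel1l, differed by −0.13 to 0.10.

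**Figure D1:**
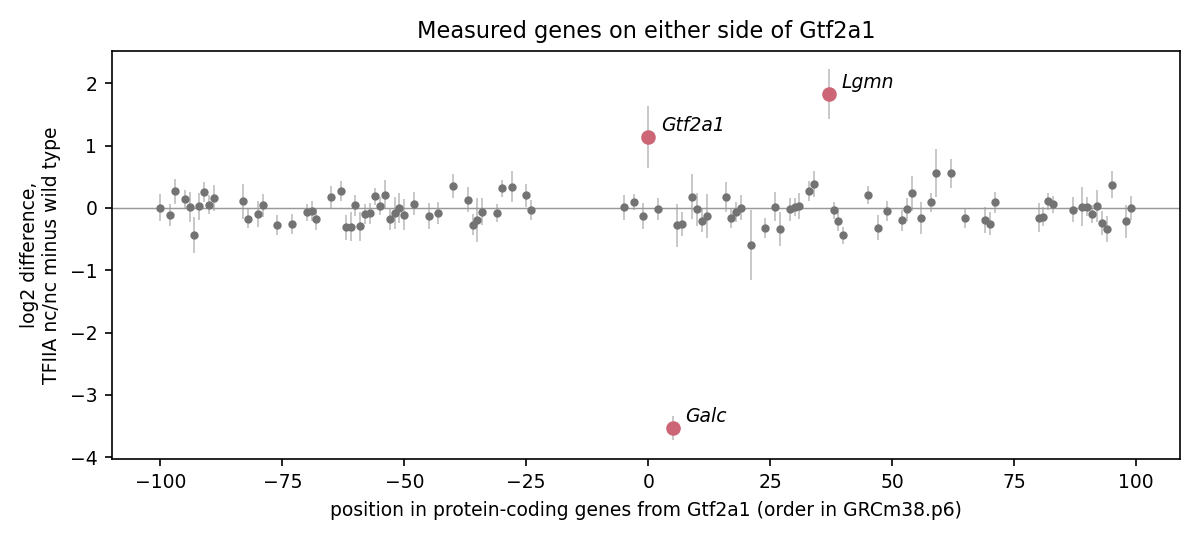
Log2 difference between TFIIA nc/nc (n = 3) and wild type (n = 4), with its SE as bars, for the measured genes up to 100 protein-coding genes on either side of Gtf2a1, by position in gene order. Galc, at −3.54 and 5 genes from Gtf2a1, lies far below the rest, and Lgmn, at 1.83, lies 37 genes away.

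Galc was the only gene of 12393 past the threshold, with 0 higher and 1 lower in TFIIA nc/nc. At an unadjusted limma p under 0.05 there were 250 higher and 299 lower genes, 549 in all, where chance alone gives 619.65. The 3 TFIIA nc/nc values lay wholly above or below the 4 wild-type values for 781 genes, 6.30% against 5.71% by chance. Among 23 alternative settings the adjusted p of Galc ranged from 4.36e-05 to 0.128, and it missed the threshold without moderation of the spread (0.128, difference −3.54) and with only the 4 arrays of low endothelial transcripts (0.0621, difference −3.80). Without wild-type replicate 1, 3 genes passed, Galc and the higher Clec1b (3.22) and Vcam1 (2.69).

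The 11 genes next in order of p among those measured lower did not pass the threshold, and in each all 3 TFIIA nc/nc samples lay below every wild-type sample. Plac8, abundant in blood progenitors, had log2 levels of 7.36 ± 0.08 (SD, n = 3) in TFIIA nc/nc and 8.40 ± 0.18 (SD, n = 4) in wild type (difference −1.05, SE 0.15; limma, Benjamini-Hochberg adjusted p = 0.285). The unnamed gene Gm6958 differed by −1.54 (SE 0.23) at the same adjusted p. Differences were −1.08 for the heparan sulfate proteoglycan Sdc1, −0.95 for the cytokine Il15, −0.85 for the P-selectin ligand Selplg and −0.73 for H2-DMa, a chaperone of antigen presentation. They were −0.86 for Ramp1, a subunit of neuropeptide receptors, −1.05 for the orphan receptor Gprc5b, −0.95 for AW112010, −0.78 for the mucin Muc5b and −0.78 for Wfdc2. Muc5b was dim, at 3.03 in wild type. The other Sdc1 probe sets, dimmer at 3.89, 3.32 and 2.46 in wild type, differed by only −0.50, −0.12 and −0.02.

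The 12 genes of smallest p among those measured higher did not pass either. Ccnd1, the G1 cyclin D1, had log2 levels of 7.58 ± 0.23 (SD, n = 3) in TFIIA nc/nc and 6.63 ± 0.05 (SD, n = 4) in wild type (difference 0.94, SE 0.15; limma, Benjamini-Hochberg adjusted p = 0.36), and its other probe sets differed by 0.95 and 0.85. Bcl2l2, an inhibitor of apoptosis, differed by 0.78 (SE 0.15), Aen, a nuclease induced by p53, by 0.72 (SE 0.15) and the mitochondrial nuclease Endog by 0.65. Adjusted over the list alone, Bcl2l2 passed among the 19 apoptosis regulators and Aen among the 24 p53 targets (limma, adjusted p = 0.00917 and 0.0183), and neither passed over all genes. A dimmer Bcl2l2 probe set, at 2.60 in wild type, differed the other way by −0.44 (exact permutation p = 0.0286). Lgmn, a lysosomal protease, differed by 1.83 (SE 0.40), and Gnai1, a G protein subunit whose groups overlapped, by 1.76. The remaining differences were 0.85 for Nucb2, 0.87 for Rbmx2, 0.83 for Bmp2k, 0.96 for Tmem184c, 0.66 for the phosphodiesterase Pde8a and 0.60 for the lipid carrier Apom. Nucb2, Pde8a and Apom were dim, at 2.79, 3.58 and 3.20 in wild type against array medians of 3.69 to 3.82. A dimmer Pde8a probe set, at 2.40 in wild type, differed by −0.15 (exact permutation p = 0.371).

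**Figure D2:**
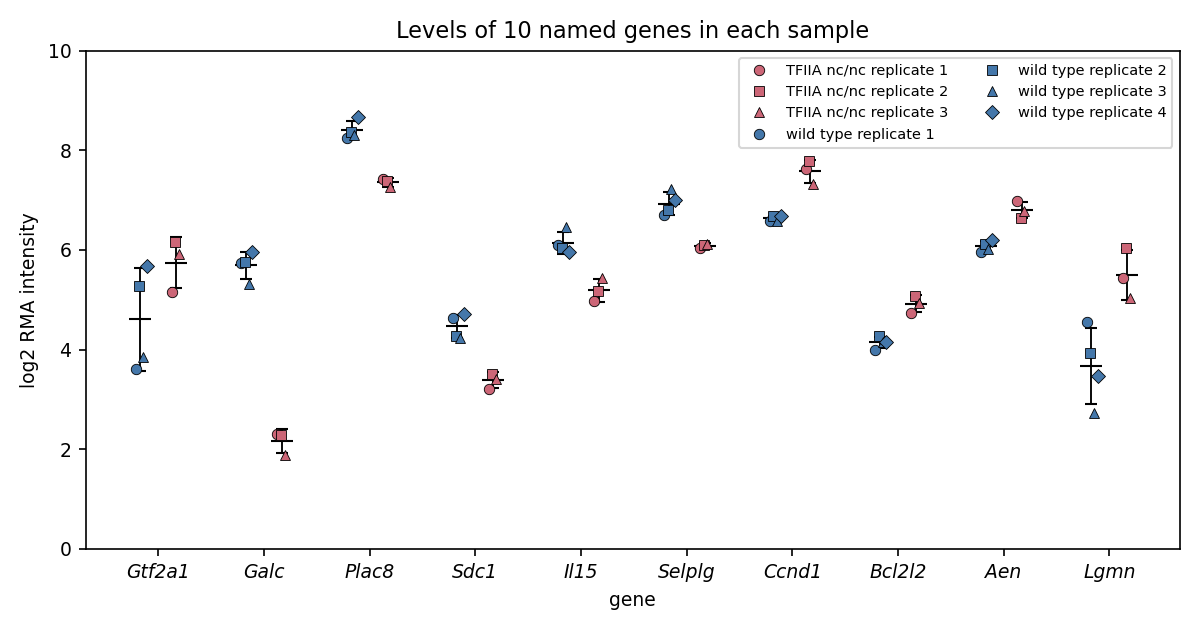
Log2 RMA intensity of 10 named genes in each of the 4 wild-type and 3 TFIIA nc/nc samples, with the mean as a horizontal line and the SD as bars. Galc alone passed the threshold, with TFIIA nc/nc samples at 1.88 to 2.31 and wild-type samples at 5.31 to 5.96.

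Of the 31 gene lists, 12 passed with camera's preset correlation, 8 higher and 4 lower in TFIIA nc/nc. With an estimated correlation 0 passed, and by fry 1 passed, the granulocyte and monocyte genes, which are not among the 12. No member of any list passed over all genes, and adjusted over the list alone 1 member passed in each of 3 lists, Lgmn, Bcl2l2 and Aen.

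Interferon-stimulated genes, stem cell genes, lymphoid genes and Hox genes had lower means in TFIIA nc/nc and passed with the preset correlation alone. The exact permutation p of the list mean was 0.171, 0.0857, 0.0571 and 0.114. For interferon-stimulated genes TFIIA nc/nc replicate 3, at 4.665, lay above wild-type replicates 1 and 3, at 4.638 and 4.621. For stem cell genes TFIIA nc/nc replicate 3, at 6.536, lay above wild-type replicate 1, at 6.527, which had high endothelial transcripts. Of 23 interferon-stimulated genes 19 were lower, with a mean difference of −0.37 (limma camera, Benjamini-Hochberg adjusted p = 5.3e-06; adjusted p = 0.541 with an estimated correlation). Rsad2, an antiviral effector, differed by −0.80 (SE 0.19), the transcription factor Irf1 by −0.52 (SE 0.15) and the immunoproteasome subunit Psmb8 by −0.63 (SE 0.19), and 9 members had an unadjusted p under 0.05. Of 34 genes of stem cell identity and self-renewal 23 were lower, with a mean of −0.20 (camera adjusted p = 0.000775; adjusted p = 0.541 with an estimated correlation). Among them Pdzk1ip1 differed by −0.76 (SE 0.23), Mllt3 by −0.77 (SE 0.25) and Gfi1, a repressor that restrains stem cell cycling, by −0.77 (SE 0.29). Mllt3 and Gfi1 read 6.129 and 6.351 in wild-type replicate 1, below 6.328 and 6.726 in TFIIA nc/nc replicate 3, while the Pdzk1ip1 groups did not overlap. With the endothelial mean as a covariate the stem cell mean was −0.147 (camera adjusted p = 0.00843, and 0.503 with an estimated correlation). Of 19 lymphoid genes 16 were lower, with a mean of −0.20 (camera adjusted p = 0.00998; adjusted p = 0.541 with an estimated correlation), led by the cytokine receptor Flt3 at −0.77 (SE 0.24) and the chromatin organiser Satb1 at −0.78 (SE 0.27). Of 31 Hox genes 23 were lower, with a mean of −0.12 (camera adjusted p = 0.048; adjusted p = 0.541 with an estimated correlation). Hoxb9, Hoxa13 and Hoxd13, at wild-type levels of 2.66, 2.72 and 2.51, differed by −0.49, −0.48 and −0.51. The Hox list was dim, with a wild-type mean of 3.00 against array medians of 3.69 to 3.82. Of brighter members, Hoxa9, at 9.12 in wild type, differed by −0.28, and Hoxa5 and Hoxa7, at 6.32 and 5.10, by 0.09 and 0.05. The lymphoid call ended without TFIIA nc/nc replicate 2 (adjusted p = 0.0738) or wild-type replicate 1 (0.153), and the Hox call without TFIIA nc/nc replicates 2 (0.146) or 3 (0.131) or wild-type replicates 1 (0.127), 2 (0.149) or 3 (0.119). With the 4 arrays of low endothelial transcripts, which hold 1 TFIIA nc/nc sample, the preset call ended for the lymphoid (adjusted p = 0.351, mean −0.106) and Hox lists (0.147), passed for the interferon (0.00253) and stem cell lists (0.0027), and had an adjusted p of 0.717 with an estimated correlation for each of the 4. The lymphoid and Hox calls also ended with pooled samples only (0.233 and 0.393) and with the sex measure, Y-linked minus Xist level, as a covariate (0.286 and 0.37). The Hox call ended as well with the probe set of largest interquartile range (0.118), among probe sets above the median level (0.484), with the number of embryos as a covariate (0.0962), and with quantile (0.118) or cyclic loess normalization (0.189). The lymphoid mean was −0.337 above the median level and −0.391 with a filter of log2 6 on at least 3 arrays.

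Genes of oxidative phosphorylation, the transcription machinery, protein folding and G2 and M phase had slightly higher means in TFIIA nc/nc and passed with the preset correlation alone. The exact permutation p of the list mean was 0.0571, 0.143, 0.171 and 0.429. Of 62 genes of oxidative phosphorylation 48 were higher, with a mean of 0.11 (limma camera, Benjamini-Hochberg adjusted p = 0.000775; adjusted p = 0.541 with an estimated correlation). Cytochrome c, Cycs, differed by 0.38 (SE 0.15), and the complex I subunits Ndufa5 and Ndufs1 by 0.64 (SE 0.25) and 0.40 (SE 0.19). Of 27 general transcription factors and Mediator subunits 20 were higher, with a mean of 0.12 (camera adjusted p = 0.00819; adjusted p = 0.541 with an estimated correlation). Gtf2h1 of TFIIH differed by 0.56 (SE 0.15), the TFIID subunits Taf13 and Taf7 by 0.68 (SE 0.22) and 0.52 (SE 0.18), and Polr2a, the largest RNA polymerase II subunit, by 0.44 (SE 0.16). Of 17 heat shock genes and chaperones 13 were higher, with a mean of 0.14 (camera adjusted p = 0.00998; adjusted p = 0.541 with an estimated correlation), led by Hsph1 at 0.54, Hspd1 at 0.53 and Dnaja1 at 0.39. Of 34 genes of G2 and M phase 24 were higher, with a mean of 0.09 (camera adjusted p = 0.0462; adjusted p = 0.743 with an estimated correlation), among them the kinetochore gene Ndc80 at 0.34 and the kinesin Kif23 at 0.25, while Nusap1 differed by −0.26. The G2 and M call ended without TFIIA nc/nc replicate 2 (adjusted p = 0.968) or wild-type replicates 1 (0.127), 2 (0.149) or 3 (0.119). The transcription factor and heat shock calls ended without TFIIA nc/nc replicate 2 (0.0812 and 0.185), TFIIA nc/nc replicate 3 (0.0812 and 0.0785) or wild-type replicate 1 (0.127 and 0.082). The mean of G2 and M genes was 0.00214 without TFIIA nc/nc replicate 2 and 0.138 without replicate 1, that of heat shock genes 0.0889 and 0.208, and that of oxidative phosphorylation 0.0735 without wild-type replicate 3. With the 4 arrays of low endothelial transcripts, which hold 1 TFIIA nc/nc sample, the preset call ended for G2 and M genes (adjusted p = 0.944, mean 0.0186), transcription factors (0.0555) and heat shock genes (0.0735) and passed for oxidative phosphorylation (7.25e-05, mean 0.202). The adjusted p with an estimated correlation was then 0.992 for G2 and M genes and 0.717 for the other lists. With pooled samples only the G2 and M (0.393), transcription factor (0.554, mean 0.0564) and heat shock (0.202) calls ended. The G2 and M and transcription factor calls also ended with the sex measure (0.247 each) or the number of embryos as a covariate (0.0644 and 0.0621), above the median level (0.185 and 0.056) and with the log2 6 filter (0.334 and 0.0927). The G2 and M call ended with the endothelial mean as a covariate (0.232) and with quantile (0.131) or cyclic loess normalization (0.269), and the transcription factor call with the probe set of largest interquartile range (0.0701, mean 0.0802). The mean of oxidative phosphorylation was 0.201 with the sex measure.

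Genes of macrophages, endothelium, liver parenchyma and the fetal stem cell programme had higher means in TFIIA nc/nc and passed with the preset correlation alone. The endothelial, liver and fetal lists were high in TFIIA nc/nc replicates 1 and 2 and wild-type replicate 1 and not in TFIIA nc/nc replicate 3, so they did not separate the genotypes (exact permutation p of the list mean 0.4, 0.257 and 0.171). The macrophage list did not separate them either (exact permutation p = 0.2), with wild-type replicates 1 and 2 at 4.251 and 4.194 and TFIIA nc/nc replicate 1 at 3.833. Of 19 macrophage genes 15 were higher, with a mean of 0.68 (limma camera, Benjamini-Hochberg adjusted p = 0.000775; adjusted p = 0.541 with an estimated correlation), led by Lgmn, the adhesion molecule Vcam1 at 2.00 (SE 0.65) and the haem-degrading enzyme Hmox1 at 1.14 (SE 0.47). Adjusted over the list alone Lgmn passed (limma, adjusted p = 0.0235), and the list's call ended without TFIIA nc/nc replicate 3 (0.277), while its mean was 0.442 without wild-type replicate 3. Of 20 endothelial genes 15 were higher, with a mean of 0.83 (camera adjusted p = 0.0186; adjusted p = 0.743 with an estimated correlation). Lyve1, the hyaluronan receptor of liver sinusoids, read 9.60 and 9.83 in TFIIA nc/nc replicates 1 and 2 and 9.73 in wild-type replicate 1, and 2.78 to 3.65 in the other 4 arrays. The members with the smallest p were Vwf at −0.40, Plvap at 1.78 (SE 1.00) and the junction cadherin Cdh5 at 1.85 (SE 1.08). Of 22 hepatoblast and hepatocyte genes 18 were higher, with a mean of 0.40 (camera adjusted p = 0.00347; adjusted p = 0.541 with an estimated correlation). Ahsg differed by 0.47 (SE 0.15), Apoa1 by 0.94 (SE 0.30) and Krt18 by −0.58 (SE 0.22), and albumin, Alb, read 6.62, 7.44 and 6.12 in the 3 arrays with high endothelial transcripts and 1.84 to 2.74 in the others. Of 14 genes of the fetal stem cell programme 11 were higher, with a mean of 0.49 (camera adjusted p = 0.00998; adjusted p = 0.541 with an estimated correlation). The transferrin receptor Tfrc differed by 0.71 (SE 0.20), Peg3 by 1.15 (SE 0.38) and Grb10 by 0.35 (SE 0.19), and the imprinted gene Mest read 8.97 to 9.52 in the 3 arrays and 3.35 to 4.00 in the others.

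With the endothelial mean as a covariate the mean difference was 0.12 for the liver list (camera adjusted p = 0.159), 0.12 for the fetal list (0.159) and 0.67 for the macrophage list (1.51e-05; adjusted p = 0.601 with an estimated correlation). Without TFIIA nc/nc replicate 2 the mean was 0.346 for the endothelial (adjusted p = 0.968), 0.162 for the liver (0.38) and 0.29 for the fetal list (0.146). Without TFIIA nc/nc replicate 3 these means were 1.59, 0.70 and 0.815, and the endothelial mean was 0.549 without TFIIA nc/nc replicate 1 and 1.36 without wild-type replicate 1. With the 4 arrays of low endothelial transcripts, 1 of them TFIIA nc/nc, the mean was −0.17 for the endothelial (camera adjusted p = 0.0735), −0.07 for the liver (0.552), 0.07 for the fetal (0.545) and 1.28 for the macrophage list (3.4e-19; adjusted p = 0.717 with an estimated correlation). With the sex measure as a covariate the endothelial (0.454), liver (0.281) and fetal (0.147) calls ended, and the macrophage mean was 1.54. These 3 calls also ended above the median level (0.1, 0.741 and 0.079) and with the log2 6 filter (0.117, 0.914 and 0.261), where camera turned the liver list's direction while its mean was 0.41 and 0.72. With pooled samples only the mean was 1.31 for the endothelial and 1.16 for the macrophage list. The endothelial call also ended without TFIIA nc/nc replicate 1 (0.222) or wild-type replicates 2 (0.249), 3 (0.0614) or 4 (0.18).

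**Figure D3:**
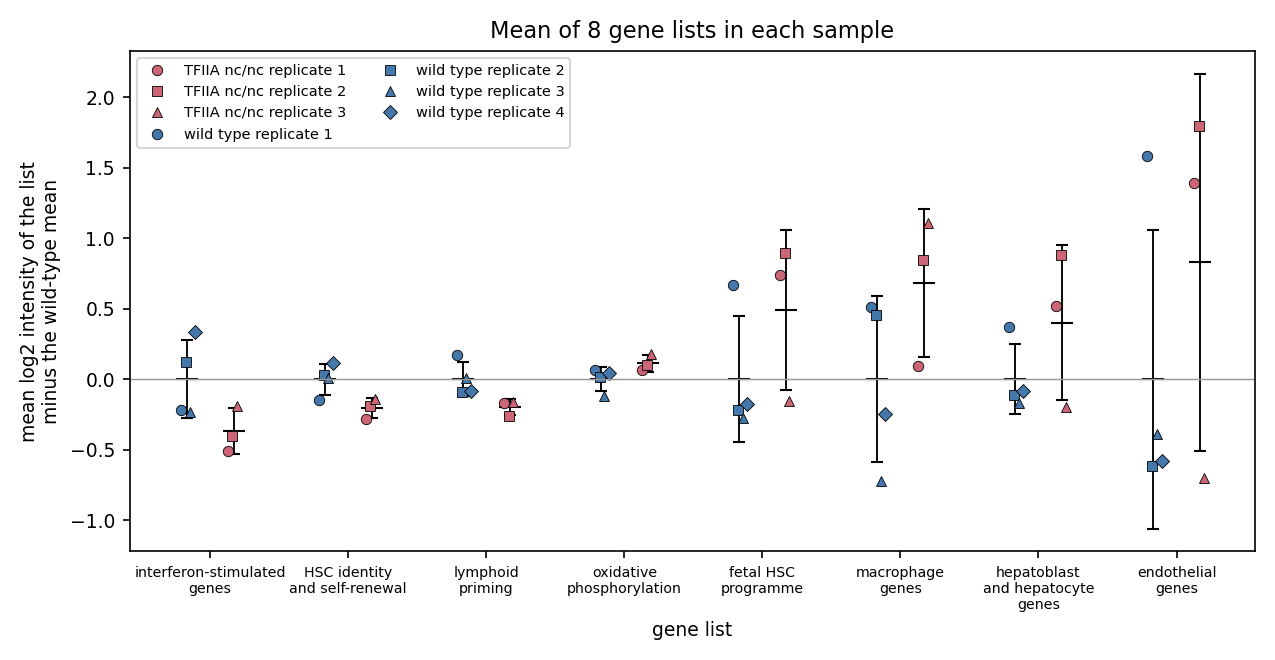
Mean log2 intensity of 8 gene lists in each of the 4 wild-type and 3 TFIIA nc/nc samples, as the difference from the wild-type mean, with the group mean as a horizontal line and the SD as bars. Interferon-stimulated genes averaged −0.37 in TFIIA nc/nc, and the endothelial list was high in wild-type replicate 1 (1.58) and TFIIA nc/nc replicates 1 (1.39) and 2 (1.80).

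The other 19 lists did not pass with limma's camera. Granulocyte and monocyte genes averaged −0.15 with 15 of 22 lower (adjusted p = 0.0625), led by the neutrophil protease Prtn3 at −1.01 (SE 0.30), lysozyme Lyz2 at −0.82 (SE 0.25) and the myeloid regulator Spi1 at −0.82 (SE 0.34). Genes of S phase averaged 0.07 (0.0958), those of the unfolded protein response 0.09 (0.119), male germ cell genes −0.09 (0.186), immediate early genes 0.12 (0.359) and inhibitors of cyclin-dependent kinases −0.08 (0.359). Orc1 differed by 0.39, Vldlr by −0.58, Tssk3 by −0.44, Junb by −0.62 and Cdkn1c by 0.51, the smallest p of each of these lists. Stromal genes averaged 0.23 (0.477), apoptosis regulators 0.08 (0.477), core histones −0.09 (0.498), ribosomal proteins −0.04 (0.558), p53 targets 0.04 (0.56) and erythroid genes 0.14 (0.644). Leaving out 1 array gave means of 0.0117 to 0.0820 for p53 targets and 0.0477 to 0.276 for erythroid genes. The 5 measured X-inactivation and Y-linked genes averaged −0.07 (0.693). Xist differed by 3.27 and Tsix by 0.19, against −1.67 for Eif2s3y, −1.29 for Kdm5d and −0.85 for Uty, so this mean does not measure embryo sex. Genes of T and NK cells averaged 0.01 (0.947), of mast cells 0.01 (0.947), of TFIIA and Taspase1 0.14 (0.959), of glycolysis 0.00 (0.959), of cholesterol synthesis −0.02 (0.988) and of megakaryocytes 0.09 (0.988). Mean, median and direction of the test differed in sign for the TFIIA, mast cell, glycolysis and megakaryocyte lists. At the preset correlation or by fry, 6 of the 19 lists passed in at least 1 other setting, and none did with an estimated correlation. S phase genes passed in 6 of 26 settings, such as with the endothelial mean as a covariate (0.00843, mean 0.127) and without TFIIA nc/nc replicate 1 (0.0057, mean 0.121) or wild-type replicate 4 (0.0083, mean 0.119), and had a mean of 0.0154 without wild-type replicate 1 (0.614). Granulocyte and monocyte genes passed in 6 of 25, such as above the median level (0.0051, mean −0.478) and without wild-type replicate 3 (0.0486). Male germ cell genes passed in 4 of 24, among them without TFIIA nc/nc replicate 1 (0.0212, mean −0.155) or wild-type replicate 4 (0.0489), and the unfolded protein response in 3 of 26. Stromal genes passed only without TFIIA nc/nc replicate 3 (0.0169, mean 0.513) and immediate early genes only without wild-type replicate 1 (0.0318, mean 0.234). The lowest means on leaving out 1 array were 0.0194 for stromal and 0.0600 for immediate early genes.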

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

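The tests of endothelial transcripts behind the Galc and interferon differences, of genotype and labelled RNA behind the endothelial transcripts, and the need for an interval without 0 in the interferon tests were chosen after the results were seen.

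In 5 of 64 values tested for a wild-type sample far from the others, 1 sample stood apart, where chance alone gives 3.2 at about 1 in 20. Wild-type replicate 1 had a mean log2 level of 7.132 for the fetal stem cell programme (6.189 to 6.285 in the other wild-type samples), 3.787 for liver parenchyma genes (3.251 to 3.337) and 6.643 for endothelial genes (4.445 to 4.667). Wild-type replicate 3 had 5.62 for apoptosis regulators (5.741 to 5.753). Wild-type replicate 2 had 3.094 for Apom (3.225 to 3.243).

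Endothelial transcripts were high in TFIIA nc/nc replicates 1 and 2 and wild-type replicate 1. Genotype alone does not give this pattern, since the lowest TFIIA nc/nc mean of the endothelial list lay at −2.28 from the highest wild-type mean. That value restates the pattern and is no separate test. The hybridisation controls of 1 of the other 4 arrays lay within the range of the 3. These controls are spiked in and do not measure the sample's own RNA, so the amount of labelled RNA is left open. Sinusoidal endothelial cells in these sorts, or their RNA, are a candidate source. A second list of 27 measured sinusoidal genes, written before its values were seen, lay at least 1.6 log2 units higher in each of the 3 arrays. In all 3 arrays 17 genes were higher, such as Oit3 at 6.96 to 8.15 against 2.10 to 2.91. The 3 arrays were known when that list was written, and genes of other endothelium were not compared, so it does not single out sinusoidal cells. The requirement for c-Kit and CD150 would remove most endothelial cells, yet Lyve1 read 9.60 to 9.83 in these arrays against 2.78 to 3.65 in the others. Of the 20 genes of the first list, 4 are also stem cell genes. Without them the mean of the other 16 was 6.55 to 6.97 in the 3 arrays against 4.097 to 4.404, so those 4 do not account for the pattern. Liver parenchyma RNA, with Alb at 6.12 to 7.44 in the same arrays, was not tested as a source.

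Galc was lower in all 3 TFIIA nc/nc samples. Endothelial cells are argued against, since the difference was −3.62 with the endothelial mean as a covariate and −3.54 without it (SE 0.19). A segment of the donor strain around Gtf2a1, inherited with the mutation, and an effect of the mutation cannot be told apart: Galc lies 5 genes from Gtf2a1, where 0.0403% of tested genes lie as close, but the 102 other measured genes within 100 genes of Gtf2a1 ranked at the percentile 34.8 of equally wide windows by median test statistic. That Galc shares the chromosome was known before the test. A sequence variant under the probes may also lower the signal, and 0 other Galc probe sets had a mean level of at least 5 to decide it.

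For the count of genes past the threshold, 3 of the 35 splits of the arrays into 3 and 4 gave at least as many genes as the genotypes, 1 of them the genotypes themselves, so by this count alone chance cannot be excluded. The count says nothing of the size of the Galc difference, which passed over 12393 genes (limma, adjusted p = 0.000171). The genotypes gave 1 gene and the highest other split gave 238, a structure of the samples, since that split sets the 3 arrays with high endothelial transcripts against the other 4.

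Interferon-stimulated genes averaged −0.369 in TFIIA nc/nc (95% interval over arrays −0.837 to 0.0984). With the endothelial mean as a covariate the value was −0.253 (−0.72 to 0.214) and with the sex measure −0.278 (−1.01 to 0.456), so neither explanation can be told apart from an effect of genotype, as both intervals hold 0 and the value without the covariate, although the list still passed camera at the preset correlation with each (adjusted p = 0.00136 and 0.0186) and 0 lists passed with an estimated one. That outcome rests on the need for an interval without 0: both values lay past the bounds set to exclude these explanations, the one for the sex measure written before its value was seen, and without that need both would have been argued against. Genes of the list that vary together over the arrays are a further candidate source, with an estimated correlation between them of 0.184. In 6 of the 35 splits, the genotypes included, the mean was as large in size, the highest other at 0.43. That count restates the exact permutation p of 0.171 and does not test whether the genes vary together.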

How the results depend on the processing

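The endothelial covariate, the 4 arrays with low endothelial transcripts and the separate test of probe sets without a single gene name were chosen after the results were seen. Against 1 gene past the threshold, 0 higher and 1 lower, the count was 0 with probe sets above log2 6 on at least 3 arrays, which leaves Galc out, 0 without moderation, 0 with the 4 arrays, where TFIIA nc/nc has 1 sample assumed to vary like the others, and 0 among probe sets without a single gene name. It was 2 with the number of pooled embryos as a covariate (Lgmn higher), 3 with pooled samples only (1 higher, Vcam1, and 2 lower, Wdfy1 and Galc) and 3 with the sex measure (2 higher, Slc40a1 and Cd5l). Leaving out 1 array gave 1 to 3 genes, 0 to 2 of them higher and 1 lower, and 3 came without wild-type replicate 1. Galc passed in 21 of 23 alternatives, with differences of −3.80 to −1.27, the latter as the mean of its probe sets, and did not shrink in the 2 that missed, which have fewer degrees of freedom for the spread. Against 12 gene lists past the threshold, the count was 0 with an estimated correlation, 1 by fry (not one of the 12), 7 above the median level, 5 with the log2 6 filter, 7 with pooled samples only, 5 with the sex measure and 4 with the 4 arrays, and leaving out 1 array gave 4 (without TFIIA nc/nc replicate 2) to 13. Camera's direction for the liver list turned above the median level (adjusted p = 0.7406) and with the log2 6 filter (0.9138), although its mean stayed higher, at 0.41 and 0.72. The liver list's mean turned with the 4 arrays (0.5522), and the endothelial list's with the endothelial covariate (0.542), which is made of its own genes, and with the 4 arrays (0.07351); fewer genes or arrays enter there, and otherwise the cause was not tested. The replicate number as a block gave 1 gene, Galc at −3.45 (adjusted p = 0.00647), a Gtf2a1 difference not past the threshold and 16 lists; same-numbered samples correlated at 0.364, −0.145 and 0.0482 in their deviations, so the numbers are not taken to pair them. Named genes other than Gtf2a1 kept direction and side of the threshold in 553 cases, with 1 newly past and 2 no longer past it. Of these genes only Galc passed in the main fit, so for the others keeping the side means staying short of the threshold. They were also picked by p from the same arrays. Signal near background limits dim probe sets, such as Galc in TFIIA nc/nc.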

Other observations

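The test for change in either direction and the naming of Hbb-y were chosen after the results were seen.

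The p53 target genes passed as a list by fry's mixed test, which counts changes in either direction without testing each (Benjamini-Hochberg adjusted p = 0.00743 over the 31 lists), while their mean was 0.04. Aen differed by 0.72 and the BH3-only gene Pmaip1 by 0.42. Pmaip1 read 1.43 to 2.32, below the first quartile of all probe sets in each array (2.24 to 2.47), so its difference lies near background. Trp53inp1 differed by −0.71, the adenylate kinase Ak1, dim at 3.48 in wild type, by −0.63 and the stress sensor Sesn1 by −0.56. None passed over all genes, and adjusted over the list alone only Aen did (limma, adjusted p = 0.0183, against 0.0528, 0.0528 and 0.0657 for these 3). With the endothelial mean as a covariate the mixed adjusted p was 0.0592. Granulocyte and monocyte genes, lower in TFIIA nc/nc, passed fry's directional test (adjusted p = 0.0171; camera adjusted p = 0.541 with an estimated correlation), with Mpo at −0.44 and Prtn3 at −1.01, and the adjusted p was 0.115 with the endothelial mean as a covariate.

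Hbb-y, an embryonic globin, read 7.93 in TFIIA nc/nc replicate 3 and 2.46 to 4.63 in the other 6 samples. The macrophage genes Cd5l and Marco were also highest there, at 6.87 and 5.22, against 2.88 to 5.88 and 2.42 to 3.78 elsewhere. Hybridisation controls ranged from 10.5 to 13.1 over the arrays on the log2 scale.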
